A study of Mus musculus with 10 samples.

How the data were processed

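RNA was measured in 10 mouse liver libraries, 4 from mice bearing a T cell-low tumour and 6 from mice bearing a T cell-high tumour, the tumours being grown from clonal cell lines of KPC pancreatic cancer. Libraries were made from total liver RNA with a 3′ end counting kit (QuantSeq FWD), per the labels' protocols, so that reads come from the ends of transcripts. Per the submitters' processing notes, STAR, DESeq2 and the mouse build mm10 were used, with no version of either tool. The annotation and the read counter are not given in the sources used here.

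The deposited table holds, for 24972 gene symbols, a signal per library that the authors made by scaling gene counts to a common depth. These values are not whole numbers. Low values fall on multiples of a step that differs between libraries, but only for a part of the genes, so whole reads could not be read back and no counting interval or floor was computed. An exact 0 in this table may be a failed estimate as well as an absence of reads, and no fold is given against a group listed at 0 in every library. Below, a value of this table is called a scaled count.

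Groups and replicate numbers were taken from the sample titles, and each column was matched to its sample by the label the submitters gave it. Genes with a mean of at least 10 scaled counts over the 10 libraries were tested (11110 genes). The log2 of the scaled count plus 1 was compared between the groups with the moderated test of limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean, no robust option and group as the only term. All p-values were two-sided, Benjamini-Hochberg adjusted over the genes tested, and called below 0.05. The moderated test had 13.1 degrees of freedom. Log2 fold changes are T cell-low minus T cell-high, and for many of them the standard error (SE) follows. Means are given with the SD over 4 T cell-low and 6 T cell-high libraries. The design had named a quasi-likelihood test for whole counts, with this test in its place for scaled values, and the second applied.

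36 gene lists were fixed before the data were examined. They cover acute phase, cytokine and interferon responses, plasma proteins, drug, bile acid, lipid, sugar and amino acid metabolism, stress, clock, cell cycle, sex-biased, matrix, zonation and RNA quality genes, and markers of 10 cell types. A list needed 3 tested members, which left 35, because 0 of the 15 mitochondrially encoded genes are in the table used here. Each list was compared with all other genes by camera, with a preset correlation of 0.01 and again with an estimated correlation, and by fry, a rotation test that asks whether a list's genes move on balance in one direction. Adjusted p-values of lists are over the 35 lists. With the preset correlation camera called a median of 9 lists in other splits of the libraries, described below. Its small adjusted p-values are therefore weak evidence alone. A list's value in a library is the median, over its tested genes, of the log2 difference from the T cell-high mean. The acute phase list includes genes of the family named in the series title, so it is not independent of the study's choice.

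Genes were named by a rule fixed before the data were examined. It takes the 4 serum amyloid A genes, the 12 largest called fold changes in each direction among genes with a mean of at least 50 in the higher group, and up to 4 called members with the lowest adjusted p of each list. For a list with no called member it takes 1 or 2 members of highest mean, with values only. It gave 123 genes, some of which are not reported here. Any other gene in the text was chosen after its values were seen.

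Positions are from GENCODE vM21, whose assembly is the one named mm10, and symbols were matched to it for 24490 genes. A gene was taken to share its 3′ end when at least 20% of the 50-base words in the last 400 bases of its transcripts occur in another gene, and such genes are reported as uncertain. 90 of the called genes are of that kind.

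In simulated data for the same comparison (11110 genes, 50 genes at each size), the test recovered 16% of genes changed by 1 on the log2 scale, 66% at 2, 94% at 3 and 92% at 4. There were 6 false calls among 140, and at most 1 call in any of 5 simulated runs without a change. The noise was drawn independently for each gene and library, with no correlation between genes and no structure beyond the 2 groups. These rates may therefore not hold for the real libraries. Alternatives planned in advance covered rescaling, the robust option, the filter, the pseudocount, the threshold, the set test, a replicate block and each library left out. Alternatives added after seeing the data were a covariate for a library set, the comparison within the other set, removal of each library's trend on transcript length (loess, span 0.5), exclusion of genes with shared 3′ ends, and library weights. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.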

Results

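Livers of mice with T cell-low tumours were compared with livers of mice with T cell-high tumours, to ask how the liver differs between mice whose pancreatic tumours hold few or many T cells. The T cell-low libraries (n = 4) all came from mice with the line 6419c1 and the T cell-high libraries (n = 6) from mice with another line, so line and T cell class are the same contrast here. The labels do not say whether each library came from its own mouse, and p-values measure the spread between these libraries, which may be technical in part. Scaled totals ran from 7000659 to 8257373 per library with a mean of 7835100 in T cell-low and 7197700 in T cell-high libraries (p = 0.0333, exact two-sided permutation test), though T cell-low 1 had 7060777. Divided by each library's step, a measure of relative depth, the totals gave p = 0.971 (exact two-sided permutation test). The number of genes above 0 was 13843 ± 426 (SD, n = 4) in T cell-low and 13863 ± 224 (SD, n = 6) in T cell-high libraries (p = 0.924, exact two-sided permutation test).

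Of 11110 genes tested, 1420 differed between the groups, 599 higher and 821 lower in T cell-low livers. Plasma proteins of the acute phase, neutrophil transcripts and matrix genes were among the higher ones. Genes of lipid synthesis and oxidation, cytochromes P450, major urinary proteins and interferon responses were among the lower ones. Among the called genes 612 showed no overlap between the groups, and 7.39% of all tested genes did so. Free exchange of the libraries would give 0.952% by chance, but the structure described next goes against it. The median log2 fold change over all tested genes was 0.003.

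The libraries did not form 2 even groups. T cell-high 1, 3, 5 and 6 differed from all other libraries by at least 1 on the log2 scale in 53 genes, 52 of them higher in these 4, such as Hbb-bs (3465 to 9359 scaled counts against 16.2 to 215) and, as the lower one, H2-L (listed at 0 against 307 to 1477), both chosen after their values were seen. This set holds T cell-high libraries only. A group difference fitted with it as a covariate is therefore T cell-low against T cell-high 2 and 4 alone, here and below. With the set as a covariate, an alternative chosen after seeing the data, limma called 0 genes (1788 at an unadjusted p below 0.05, against 3830 without it). Within the other 6 libraries it called 0 as well (999 at an unadjusted p below 0.05). These fits give the same fold changes by construction, so the latter is no separate check. All 1420 called genes kept their direction with the covariate. They were chosen by the fit without it on the same libraries, and for the 612 without overlap the direction could not change. The kept direction is therefore little evidence. Their fold changes were a median of 0.810 times the size (interquartile range 0.642 to 0.985), and the standard error was a median of 1.31 times as large. A larger standard error follows in part from the smaller number of T cell-high libraries compared. T cell-low 1 lay apart from T cell-low 2, 3 and 4. Its mean correlation over genes was 0.861 with its own group and 0.936 with the T cell-high libraries, and 176 genes separated T cell-low 2, 3 and 4 from the other 7 libraries.

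The number of called genes depended on single libraries. It was 3633 without T cell-low 1, 2280 without T cell-high 2 and 1095 without T cell-high 4. It was 109 without T cell-low 2, 508 without T cell-low 3 and 156 without T cell-low 4, and 433, 380, 403 and 446 without T cell-high 1, 3, 5 and 6.

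**Figure D1:**
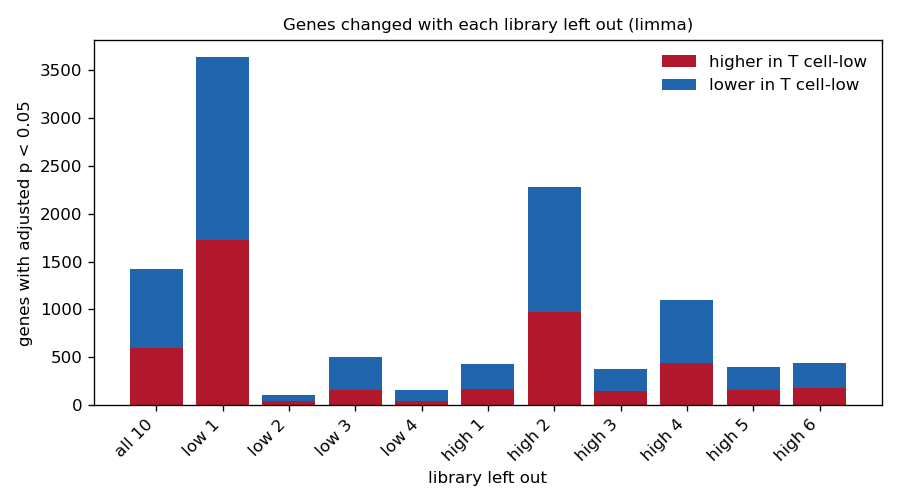
Number of genes with an adjusted p below 0.05 (y axis) with all 10 libraries and with each library left out (x axis), split into genes higher and lower in T cell-low livers. The count runs from 109 without T cell-low 2 to 3633 without T cell-low 1.

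Serum amyloid A transcripts were higher in T cell-low livers for the 2 genes that encode the circulating acute phase forms. Saa1 (chromosome 7, 46740497 to 46742980) had 24071 ± 17062 scaled counts in T cell-low and 2597 ± 2087 in T cell-high livers (log2 fold change 3.32, SE 0.68, adjusted p = 0.0169). Saa2 (chromosome 7, 46751790 to 46754313) had 20107 ± 15501 against 1329 ± 995 (3.93, SE 0.74, adjusted p = 0.0132). All 4 T cell-low libraries lay above all 6 T cell-high libraries for both genes, though for Saa1 the lowest T cell-low value (6626) was close to the highest T cell-high value (6313). Saa3, which is also made by macrophages and fat, had 159 ± 52.9 against 108 ± 47.5 (0.61, SE 0.33, adjusted p = 0.205). Saa4, the constitutive form, had 1086 ± 1062 against 2436 ± 1154 (-1.49, SE 0.52, adjusted p = 0.0688), and neither passed the test. Without T cell-low 4 the adjusted p was 0.0655 for Saa1 and 0.0506 for Saa2. Entering the library set as a covariate gave a log2 fold change of 2.72 (SE 0.90, adjusted p = 0.202) for Saa1. For Saa2 it was 3.08 (SE 0.95, adjusted p = 0.189). Saa3 then had 0.96 (SE 0.43, adjusted p = 0.300) and Saa4 -0.77 (SE 0.64, adjusted p = 0.555).

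Acute phase genes rose beyond serum amyloid A. Of the 26 members, 13 rose, 1 fell and 12 did not pass (16 higher and 3 lower when adjusted over the list alone, a list that is not independent of the study's own choice). Itih3, an inter-alpha-trypsin inhibitor heavy chain, had 33779 ± 10563 scaled counts against 7404 ± 1803 (2.16, SE 0.26, adjusted p = 0.00331). Hpx, the plasma haem carrier hemopexin, had 81088 ± 19439 against 28101 ± 7664 (1.54, SE 0.25, adjusted p = 0.00876). The member that fell was C-reactive protein, Crp (-0.91), named after its value was seen. The list median was 0.85 on the log2 scale, and the library values were 0.590 to 0.926 in T cell-low and -0.327 to 0.636 in T cell-high libraries, the highest T cell-high value being that of T cell-high 6. Camera called the list higher (adjusted p = 1.2e-05; adjusted p = 0.336 with an estimated correlation), and fry did so too (adjusted p = 0.0238). The number of called members was 2 without T cell-low 4, 4 without T cell-low 2, 6 without T cell-low 3, 7, 5 and 7 without T cell-high 1, 3 and 5, and 18 without T cell-low 1. When the library set was a covariate, 0 members passed (0 of all genes did by limma, with 1788 at an unadjusted p below 0.05), the list median was 0.97 and the adjusted p by fry was 0.0905.

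**Figure D2:**
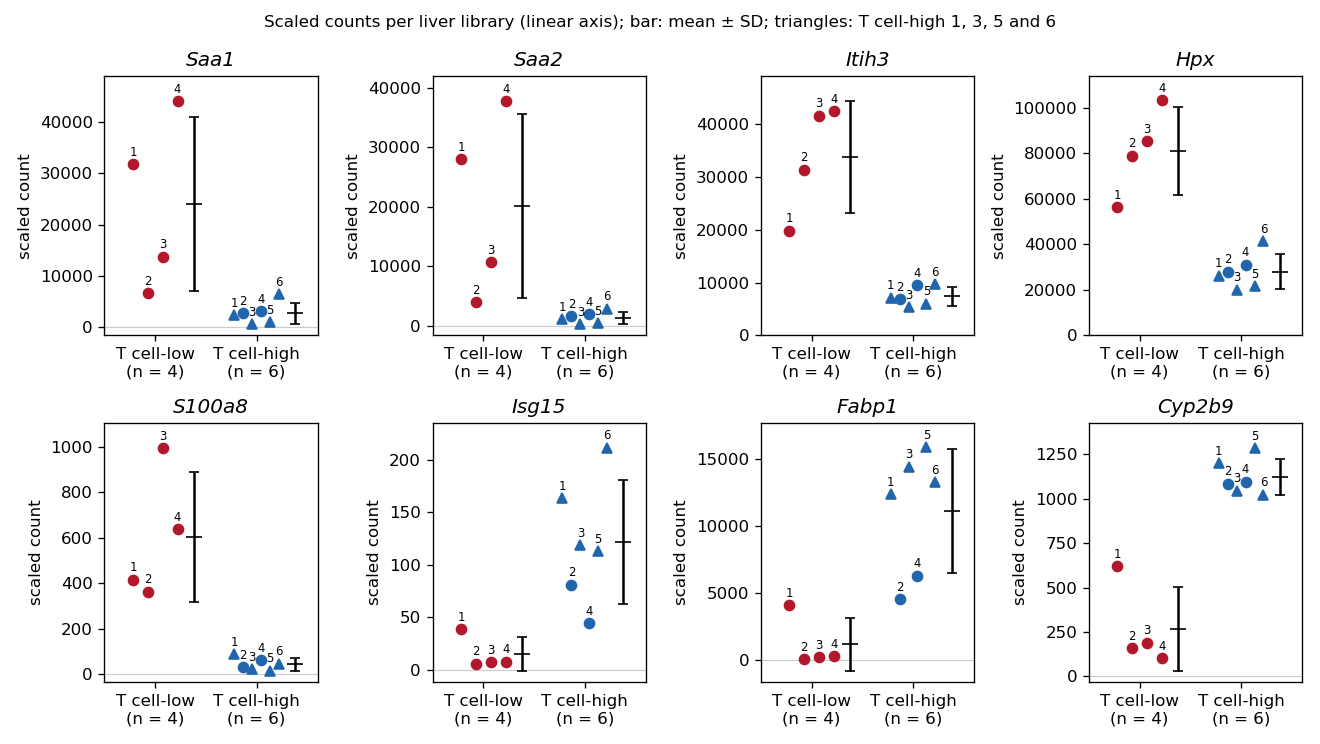
Scaled counts (y axis, linear) of 8 genes in each liver library, by group (x axis), with the replicate number at each point, the mean and SD as a bar, and triangles for T cell-high 1, 3, 5 and 6. Saa1, Saa2, Itih3, Hpx and S100a8 were higher in all 4 T cell-low libraries, and Isg15, Fabp1 and Cyp2b9 were lower in all 4, with T cell-low 1 nearest to the T cell-high libraries in the latter 3.

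Neutrophil transcripts rose in T cell-low livers. Of the 24 members 9 could be tested. Of these, 5 rose, 1 fell and 3 did not pass (6 higher and 1 lower adjusted over the list alone). S100a8 had 603 ± 287 scaled counts against 44.6 ± 28.1 (3.85, SE 0.46, adjusted p = 0.00331), and S100a9, which encodes its partner in the neutrophil protein calprotectin, had 440 ± 173 against 48.5 ± 31.6 (3.32, SE 0.48, adjusted p = 0.00595). Ngp, a granule protein, had 38.6 ± 22.3 against 1.45 ± 2.65 (4.24, SE 0.83, adjusted p = 0.0144). The member that fell, G0s2 (2.19 ± 3.84 against 169 ± 132), also encodes an inhibitor of lipolysis in hepatocytes, and Lcn2, which rose, is also in the acute phase list. The list median was 2.66 (camera adjusted p = 0.00596; adjusted p = 0.376 with an estimated correlation; fry adjusted p = 0.0248). Called members fell to 2 higher and 1 lower without T cell-low 2. The median with the set covariate was 2.28 (fry adjusted p = 0.157).

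Most other immune cell markers could not be tested or did not pass. Of the T and NK cell genes 4 of 25 were tested, and of the B and plasma cell genes 3 of 16. For monocytes and dendritic cells it was 8 of 16. The rest of these lists was absent or below the filter, so nothing can be said of it. Of the 8 tested monocyte and dendritic cell genes 3 rose, namely Chil3 (3.90, SE 0.83), Itgam (2.14, SE 0.47) and the calcium-binding protein gene S100a4 (1.53, SE 0.28, adjusted p = 0.012), whose 3′ end is shared with another gene. That list passed by fry (adjusted p = 0.0424) and not by camera (adjusted p = 0.0953), and its median was 0.14. Among Kupffer cell and macrophage genes 0 of 16 passed (fry adjusted p = 0.948). Cd5l, a Kupffer cell protein, had 2290 ± 828 against 2080 ± 1111 scaled counts, and Csf1r, the receptor for macrophage colony-stimulating factor, had 1483 ± 497 against 1383 ± 788. The set covariate turned these to -0.55 for Cd5l and -0.60 for Csf1r and the list median from 0.14 to -0.295 (camera adjusted p = 0.0691; fry adjusted p = 0.392). Within the other 6 libraries camera called the Kupffer list lower (adjusted p = 0.0287). Both rest on T cell-high 2 and 4 as the only comparators. Their list medians were 0.338 and 0.652, against -0.832 to 0.601 in the other T cell-high libraries. No tested T and NK cell gene passed (0 of 4, fry adjusted p = 0.942). The chemokine gene Ccl5 had 25.3 ± 12.8 against 23.3 ± 7.59 scaled counts, and Il7r had 32.5 ± 13.8 against 17.6 ± 6.33. For B and plasma cells 0 of 3 passed (fry adjusted p = 0.819, list median 0.10 and mean -0.05), with Sdc1 at 601 ± 209 against 924 ± 179 and the B cell gene Ms4a1 at 14.1 ± 13.9 against 9.45 ± 6.69 (0.42).

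Matrix genes rose, and so did immediate early genes, a list fixed in advance as a measure of RNA quality. A technical source of the latter rise was not tested. Of 19 tested matrix and wound response genes 5 rose and 0 fell (9 adjusted over the list alone). They included Lox, a collagen cross-linking enzyme (28.9 ± 12.6 against 5.06 ± 2.88 scaled counts, log2 fold change 2.32, SE 0.51, adjusted p = 0.0196), and the protease inhibitor gene Timp2 (1.18, SE 0.31). The list median was 0.84 (camera adjusted p = 1.8e-04; adjusted p = 0.221 with an estimated correlation; fry adjusted p = 0.00174). With the set covariate its median was 0.63 and it still passed by fry (adjusted p = 0.0335), while 0 members were called without T cell-low 2. Of 17 immediate early genes 5 rose and 0 fell (11 adjusted over the list alone), among them the antiproliferative gene Btg2 (739 ± 691 against 66.4 ± 16.3, log2 fold change 2.88, SE 0.56, adjusted p = 0.0141) and the transcription factor gene Klf6 (2.27, SE 0.49). Their list median was 1.58 (camera adjusted p = 2.5e-05; adjusted p = 0.336 with an estimated correlation; fry adjusted p = 0.033), with 0.395 in T cell-low 1 and 0.787 to 2.74 in T cell-low 2, 3 and 4, and 0 members were called without T cell-low 2. The set covariate lowered that median to 0.985, and the list did not pass (fry adjusted p = 0.22).

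Interferon response genes fell in T cell-low livers. Of 23 tested type I interferon genes 15 fell, 0 rose and 8 did not pass (16 adjusted over the list alone). The ubiquitin-like protein gene Isg15 had 14.8 ± 15.9 against 122 ± 59.3 scaled counts (-3.22, SE 0.52, adjusted p = 0.00876). Zbp1, a sensor of nucleic acids, had 8.2 ± 12.1 against 47.9 ± 33.5 (-3.04, SE 0.72, adjusted p = 0.0242). In the list of interferon gamma and antigen presentation 9 of 23 fell and 0 rose (13 adjusted over the list alone), including the immunoproteasome genes Psmb8 (52.8 ± 40.6 against 185 ± 45.4, log2 fold change -1.99, SE 0.37, adjusted p = 0.0121) and Psmb10 (-1.41, SE 0.29) and the chemokine gene Cxcl9 (-2.86, SE 0.62). The list median was -1.45 for the type I list and -1.0 for the other. Camera called both lower (adjusted p = 2.6e-08 and 2.9e-06; adjusted p = 0.336 for each with an estimated correlation), as did fry (adjusted p = 0.0191 and 0.0248). In T cell-low 1 the list medians were -0.195 and 0.021, within the range of the T cell-high libraries, against -2.47 to -1.64 and -1.84 to -1.49 in T cell-low 2, 3 and 4. The fewest called members were 1 of the type I list without T cell-low 4 and 0 of the other list without T cell-low 2. With the library set as a covariate the medians were -1.62 and -0.85 (fry adjusted p = 0.0788 and 0.197).

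Lipid metabolism genes fell. Of 21 lipogenesis genes 12 fell and 0 rose (15 adjusted over the list alone). Acacb, an acetyl-CoA carboxylase, had 66.5 ± 50.1 against 265 ± 67.7 scaled counts (-2.21, SE 0.38, adjusted p = 0.0108). The desaturase gene Fads2 had 23.7 ± 25.5 against 109 ± 18.9 (-2.61, SE 0.45), and Mlxipl, a carbohydrate-responsive transcription factor gene, had 208 ± 114 against 587 ± 82.7 (-1.65, SE 0.30). Of 24 genes of fatty acid oxidation and ketogenesis 10 fell and 0 rose (15 adjusted over the list alone). Acot1, an acyl-CoA thioesterase, had 14.6 ± 10.5 against 198 ± 98.2 (-3.83, SE 0.50, adjusted p = 0.00331). Of 22 cholesterol synthesis genes 3 fell and 0 rose (3 adjusted over the list alone), among them Sc5d and Dhcr7, which encode enzymes of the last steps of the pathway.

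Camera called these 3 lipid lists lower (adjusted p = 1.5e-08, 4.8e-07 and 3.6e-05). With an estimated correlation they were lost (adjusted p = 0.336 for lipogenesis, adjusted p = 0.221 for oxidation and adjusted p = 0.49 for cholesterol synthesis). Fry called lipogenesis (adjusted p = 0.0118) and oxidation (adjusted p = 0.00174) and not cholesterol synthesis (adjusted p = 0.158). The list medians in T cell-low 1 were -0.468, -0.307 and -0.150, nearer to 0 than in T cell-low 2, 3 and 4 for lipogenesis (-2.56 to -1.10) and oxidation (-1.75 to -0.784). For cholesterol synthesis the value was 0.427 in T cell-low 3 and -2.33 and -2.19 in T cell-low 2 and 4. Without T cell-low 2 the called members were 4, 1 and 0, and those of cholesterol synthesis were 12 without T cell-low 1 and 6 without T cell-low 3. With the library set as a covariate the medians were -1.55, -0.74 and -0.95, and the adjusted p by fry was 0.0788, 0.0335 and 0.307.

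Genes of drug metabolism and of the sex-dependent liver program fell. Of 33 tested P450 and xenobiotic genes 16 fell, 2 rose and 15 did not pass (19 lower and 2 higher adjusted over the list alone). Of 15 tested sex-biased genes 8 fell, 1 rose and 6 did not pass (11 lower and 2 higher adjusted over the list alone). Cyp2b9, a P450 of female liver, had 268 ± 236 against 1122 ± 100 scaled counts (-2.40, SE 0.37, adjusted p = 0.00836). A1bg, a plasma glycoprotein gene with female-biased expression, had 31.3 ± 61.6 against 952 ± 995 (-7.17, adjusted p = 0.00954). The glutathione transferase gene Gstm3 had 131 ± 148 against 858 ± 215 (-3.37, SE 0.55). Cyp2a4 (-3.79, SE 0.48), Cyp2c40 (-2.36, SE 0.31) and Cyp3a41a (-2.42, SE 0.28) fell as well (adjusted p = 0.00331 for each), but each shares its 3′ end with another gene, so that reads of copies may be mixed. Genes higher in male liver were on both sides. Cyp7b1 and Elovl3 fell and Cyp2d9 rose (1.46), the 3′ end of the last being shared in part. Elovl3 and Cyp2d9 were chosen after their values were seen. Xist had 866 to 2097 scaled counts over the libraries, and Ddx3y, Kdm5d, Eif2s3y and Uty of the Y chromosome were listed at 0 in all. These values argue against a difference in sex between the groups.

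Major urinary protein genes fell in 11 of 15 tested members (13 adjusted over the list alone), and 0 rose. Mup3, the member named here whose 3′ end is little shared with others (5.6% of it), had 908 ± 1050 against 7045 ± 1943 scaled counts (-3.59, SE 0.54, adjusted p = 0.00803). The log2 fold change was -3.51 for Mup1, -4.66 for Mup11 and -3.13 for Mup12, but these genes share 72.2% or more of their 3′ ends with other genes and cannot be counted apart. In T cell-low 1 the list median was -0.709, against -5.07 to -3.43 in T cell-low 2, 3 and 4.

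Pericentral and bile acid genes fell in part. Of 15 pericentral hepatocyte genes 5 fell and 0 rose (7 lower and 1 higher adjusted over the list alone), among them the aldehyde dehydrogenase gene Aldh3a2 (128 ± 99.4 against 514 ± 101, log2 fold change -2.23, SE 0.34, adjusted p = 0.00835). Of 19 bile acid genes 4 fell and 1 rose (8 lower and 1 higher adjusted over the list alone). Those that fell included Abcb11, the bile salt export pump (679 ± 647 against 2069 ± 442, log2 fold change -2.04, SE 0.45), and the one that rose was the bile acid transporter gene Slc10a2, named after its value was seen. Periportal genes went both ways, with 1 of 15 higher, Arg1 of the urea cycle, and 4 lower (fry adjusted p = 0.266), among them Cyp2f2 (-1.39, SE 0.25).

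For these 5 lists with a camera call (P450, sex-biased, major urinary protein, pericentral and bile acid genes) the adjusted p was 4.8e-07, 3.1e-05, 1.9e-07, 0.00306 and 0.0479 by camera, and 0.00712, 0.00174, 0.00712, 0.0118 and 0.0328 by fry. With an estimated correlation none passed (adjusted p = 0.292, 0.221, 0.292, 0.336 and 0.376 in that order). The camera call of bile acid genes was lost without T cell-low 1 or 4 or T cell-high 2, 4 or 5 (adjusted p up to 0.118). Without T cell-low 2 the members that fell were 8, 6, 4, 1 and 0. With the library set as a covariate the list medians were -0.91, -2.18, -2.94, -0.10 and -0.30, and sex-biased genes alone among these passed by fry (adjusted p = 0.0335).

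**Figure D3:**
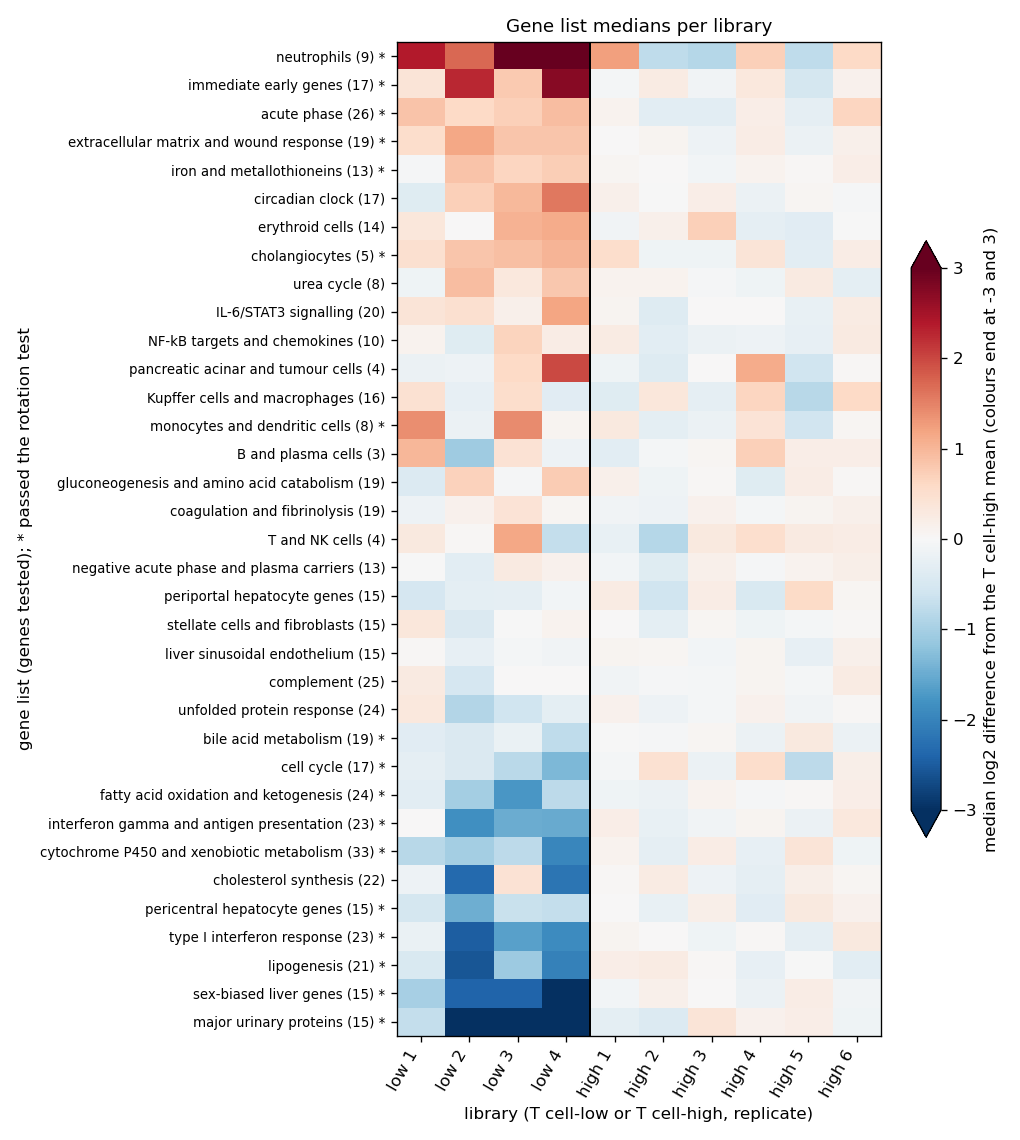
Median log2 difference from the T cell-high mean (colour) of the tested genes of each list (rows, with the number of genes tested) in each library (columns), with an asterisk where fry gave an adjusted p below 0.05. Major urinary proteins ran from -5.07 to -3.43 in T cell-low 2, 3 and 4 and -0.709 in T cell-low 1, and neutrophil genes from 1.73 to 3.05 in the 4 T cell-low libraries.

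Further lists showed few called members. Cell cycle genes had 1 of 17 lower, the thymidine kinase gene Tk1 (-1.35, SE 0.27, adjusted p = 0.0151), and 1 higher, Hmgb2, with a list median of -0.64 (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0383; adjusted p = 0.376 with an estimated correlation; fry adjusted p = 0.0489). The camera call of cell cycle genes was lost without T cell-low 1 or 4 or T cell-high 2, 4 or 6 (adjusted p up to 0.118). Without T cell-low 2, 0 members were called. With the library set as a covariate the cell cycle median was -1.4 (fry adjusted p = 0.0335; camera adjusted p = 4.6e-05). That value rests on T cell-high 2 and 4, which had the highest list medians of the T cell-high libraries. They were 0.450 and 0.523, against -0.795 to 0.179 in the others. Iron and metallothionein genes passed by fry alone (adjusted p = 0.033; camera adjusted p = 0.0967), with Hmox1 (1.25, SE 0.35) and the hepcidin regulator Hfe2 higher and Ftl1, whose 3′ end is shared, lower, of 13. Cholangiocyte genes also passed by fry alone (adjusted p = 0.0238; camera adjusted p = 0.131) with 0 of 5 members called, and Sox9 had 208 ± 140 against 119 ± 38. Of 17 clock genes 3 rose and 1 fell (fry adjusted p = 0.208), namely Tef, Cry1 and Cry2, and Npas2. Of 14 erythroid genes 2 rose (fry adjusted p = 0.137), Hba-a2, which shares its 3′ end with its copy, and the anion exchanger gene Slc4a1 (88.4 ± 46.6 against 9.89 ± 8.59, log2 fold change 3.41, SE 0.85). Of 20 genes of interleukin 6 and STAT3 signalling 3 rose (fry adjusted p = 0.158), among them the interleukin 1 receptor gene Il1r1 (2194 ± 1715 against 339 ± 103, log2 fold change 2.32, SE 0.50).

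In other lists the members went both ways or did not pass. Of 10 tested genes of NF-kB targets and chemokines 1 fell, the superoxide dismutase gene Sod2 (fry adjusted p = 0.861, list median 0.24 and mean -0.003). Of 13 plasma carriers 2 fell, the corticosteroid-binding globulin gene Serpina6 (128 ± 199 against 789 ± 144, log2 fold change -3.80, SE 0.64, adjusted p = 0.00989) and Igfals, and 1 rose, the apolipoprotein gene Apoa1 (fry adjusted p = 0.987, list median -0.01 with camera direction higher). Complement genes had 2 higher and 2 lower of 25 (fry adjusted p = 0.7), with C8g, a subunit of the membrane attack complex, at 1992 ± 926 against 4623 ± 386 (-1.34, SE 0.27, adjusted p = 0.017). Coagulation genes had 2 of 19 higher, Kng1, whose 3′ end is shared in part, and Pros1 (fry adjusted p = 0.369). Gluconeogenesis and amino acid catabolism had 1 higher, Sdsl, and 1 lower, Hgd, of 19 (fry adjusted p = 0.624), and the urea cycle had 1 of 8 higher (fry adjusted p = 0.174). The unfolded protein response had Asns higher and Hyou1 lower of 24 (fry adjusted p = 0.441). Without T cell-low 1 the called members were 2 higher and 9 lower for the unfolded protein response, 6 and 2 for coagulation, 6 and 2 for gluconeogenesis and 4 and 1 for the urea cycle. Without T cell-low 2 they were 0 in these lists but for 1 higher in gluconeogenesis. Without T cell-high 2 coagulation had 2 higher and 4 lower. Sinusoidal endothelial genes had Lyve1 and Stab2 higher and Dnase1l3 lower of 15 (fry adjusted p = 0.328). Stellate cell genes had 1 of 15 higher, Rgs5 (fry adjusted p = 0.667, list median -0.08 and mean 0.03). Of 4 tested pancreatic acinar and tumour genes, Msln rose and the elastase gene Cela1 fell (fry adjusted p = 0.948).

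The largest fold changes were carried mostly by T cell-low 2, 3 and 4. Higher in T cell-low livers were the estrogen sulfotransferase gene Sult1e1 (627 ± 450 against 8 ± 16.8 scaled counts, 5.81, adjusted p = 0.0375, with 0.862 in T cell-low 1), Tff3, Defb1, Miox, Setdb2, the imprinted non-coding RNA gene H19 (137 ± 88.6 against 3.57 ± 4.65, 5.24, SE 0.88), E030018B13Rik and the protease inhibitor gene Serpina1e (30767 ± 20160 against 1756 ± 708, 3.90, SE 0.48, adjusted p = 0.00331). Ctsj (63.3 ± 37.2) and Dph1 (152 ± 130) were listed at 0 in all 6 T cell-high libraries, and Dph1 shares its 3′ end with another gene. Lower in T cell-low livers was the carbonic anhydrase gene Car3 (481 ± 835 against 8541 ± 2027, -7.01, SE 1.27). So was Hamp2, a paralogue of the hepcidin gene Hamp (384 ± 613 against 12255 ± 3635, -6.68, SE 0.86, adjusted p = 0.00331). The fatty acid-binding protein gene Fabp1 (1138 ± 1964 against 11113 ± 4617, -5.16, SE 0.95), Eci3, A1bg, G0s2 and Oaz1-ps were lower too. With shared 3′ ends, Gm2083, Acaa1b, Mup7, Mup11 and Mup15 were also lower. Without T cell-low 2 the adjusted p was above 0.05 for Sult1e1 (0.133), Tff3 (0.0736), Miox (0.0526), Setdb2 (0.128), E030018B13Rik (0.124), Oaz1-ps (0.12), Dph1 (0.0974), Mup7 (0.0848), Acaa1b (0.0503) and Mup11 (0.0503). Sult1e1, Setdb2 and E030018B13Rik passed with 3 of the 10 libraries left out in turn, Oaz1-ps with 4, and Tff3, Dph1 and Mup7 with 7. The other genes of this paragraph passed with each library left out.

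Of the 35 lists tested, camera called 15, of which 4 were higher (acute phase, matrix, immediate early and neutrophil genes) and 11 lower. With an estimated correlation it called 0 (15 with the preset one), and fry called 17. In other splits of the libraries into 4 and 6, camera with the preset correlation called a median of 9 lists, so its calls alone are weak evidence. With the library set as a covariate fry called 4, namely matrix, fatty acid oxidation, sex-biased and cell cycle genes. Camera with the preset correlation then called 18 (20 within the other 6 libraries). These values compare T cell-low with T cell-high 2 and 4 alone.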

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

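Of the tests below, those chosen only after the results were seen are the splits for lists called by fry, the library set, transcript length for the 1420 genes, shared 3′ ends, depth, body temperature and time of day.

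Some samples lay far from the rest of their group, by the gap to the nearest sample relative to the range of the group. Among 324 groups of values 18 had such a sample, where chance alone gives about 1 in 20 groups, or 16 here. T cell-low 1 was the sample in 11 of the 18. Compared with T cell-low 2, 3 and 4, it had more transcript of Hgd (2401 scaled counts against 1254 to 1285), Isg15 (38.7 against 5.71 to 7.77), Mup11 (1464 against 32.5 to 55.1), Mup12 (249.0 against 28.4 to 34.8) and Vnn1, a pantetheinase gene (292.9 against 38.7 to 41.9). It had less of Lyve1 (157.7 against 716.4 to 843.6), Slc4a1 (19.8 against 104.8 to 123.4), Stab2 (193.4 against 339.7 to 366.7), Sult1e1 (0.862 against 632.1 to 1045) and Tff3 (2.64 against 87.7 to 142.9), and was listed at 0 for Dph1 (118.4 to 312.8 in the others). In T cell-low 3, Ccl5 had 44.5 against 17.8 to 19.5. Among the T cell-high libraries, T cell-high 2 had 16340 for Acaa1b (7335 to 9897 in the rest), and T cell-high 4 had 438.7 for Cela1 (243.6 to 281), 144.9 for Fads2 (93 to 109.5) and 592.4 for Sdc1 (869.9 to 1060). T cell-high 5 had 42.2 for Sult1e1 (0 to 2.29). The median of the pancreatic acinar and tumour cell list was 1.10 in T cell-high 4 and -0.59 to 0.04 in the rest.

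The first pattern weighed is the difference between the groups in 1420 genes. Of 100 splits of the 10 libraries into 4 and 6, 4 gave as many called genes, the real one included, with 3093 as the highest other count. The number higher was reached by 4 splits (599 real, highest other 1414) and the number lower by 2 (821 real, highest other 1679). The 14 acute phase genes were reached by 1 split, the real one (highest other 7). Few splits thus reached these counts, which would exclude chance only if the libraries could be exchanged freely. The structure described below goes against that, so the splits cannot decide it. These splits ignore the library set, and with it as a covariate 0 genes, and 0 acute phase genes, passed by limma (1788 genes at an unadjusted p below 0.05). The lists called by camera were reached by 20 splits (15 real, highest other 20, median of the others 9), so chance cannot be excluded for that count. The 17 lists called by fry were reached by 1 split, the real one (highest other 5). With the library set as a covariate, however, fry called 4 lists. The split of T cell-low 2, 3 and 4 with T cell-high 2 against the rest gave the 3093 genes, and the split of T cell-high 1, 3, 5 and 6, the library set, gave 1866. Both point to a structure of the samples, and the value with that set as a covariate is given next.

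Other tests of that difference asked whether processing may explain it. With a covariate for the library set the called genes' fold changes were a median of 0.810 times as large (interquartile range 0.642 to 0.985). These genes were chosen by the fit without the covariate, and the set holds T cell-high libraries only. The ratio therefore cannot tell how much of their size the set accounts for. The calls ended because the standard errors were larger, by a median of 1.31 times, and the fold changes smaller. With T cell-high 2 and 4 as the only comparators, a larger standard error is built into that fit. The loss of calls therefore does not show that the library set caused the difference. Once each library's trend on transcript length was removed, 82.7% of the called genes that have a length stayed called, and genes with 1 transcript were called 1.39 times as often as genes with more (95% interval 1.201 to 1.615), where scaling that differs between isoforms predicts the reverse. These tests argue against length or isoform scaling as the whole cause. The difference in tumour line, and with it in T cell class, stays among the open explanations as untested, and the effect of a batch that matches the groups cannot be tested here.

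The second pattern is the 53 genes that separate T cell-high 1, 3, 5 and 6 from the other 6 libraries. Reads shared between gene copies could explain part of it: 10 of 51 genes with a 3′ end to search share it with another gene, 19.6% against 4.62% of the other genes (odds ratio 5.03, 95% interval 2.23 to 10.3, exact two-sided Fisher p = 0.00011). The tables argue against depth, as 0 of the 4 libraries lay outside the range of relative depth of the other 6, and against length as the whole cause, as 60.8% of the genes with a length kept a gap of at least 1 after the trend was removed and all 51 stayed apart. The share of Rn45s, a precursor of ribosomal RNA, was 3.98% to 6.76% in the 4 libraries and 7.63% to 9.72% in the other 6, so that a difference in library preparation stays open. The labels give no batch for the 4 libraries, and no biological explanation was tested.

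The third pattern is that T cell-low 2, 3 and 4 lie apart from T cell-low 1. A wrong label of T cell-low 1 could explain it and stays open, though the following go with the label it has, unlike its correlations: in 5 of 6 comparisons that left out a T cell-high library, T cell-low 1 lay beyond the T cell-high range in a larger share of genes than the left-out library did (33.6% against 54.1% for the exception, T cell-high 2), and it lay beyond that range in 11 to 16 of 16 to 19 acute phase genes (0 to 2 for the left-out library, 14 for T cell-high 6). A lower body temperature may lower chaperones that follow the heat shock factor, and their median was below every other library in 3 of 3 (-0.946, -0.689 and -0.703, against 0.294 in T cell-low 1 and -0.202 to 0.434 in T cell-high), by a list and a test set after these values were seen, while with T cell-low 1 pooled among the 4 the list did not pass (fry adjusted p = 0.0594). A difference in time of day may move clock genes, and Tef (986.4 to 2256 against 303.9 to 396.9), Nr1d2, Usp2, Per3 and Dbp were higher in all 3 libraries than in every T cell-high library and Npas2 was lower, but Nr1d1, of the same phase as Nr1d2, was below the T cell-high mean of log2 values in 1 of 3 (2 of 3 for the mean of scaled counts), and the activators Arntl and Clock overlapped. Temperature and time of day both stay open, as neither is in the labels.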

How the results depend on the processing

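The tests with the library set, transcript length, shared 3′ ends and library weights were chosen only after the data were seen, and the others were planned. Rescaling, the robust option, a mean of at least 50 and pseudocounts of 0.5 and 4 gave 1342 to 1518 called genes, against 1420. With no filter 1113 genes and 9 acute phase genes passed, among more genes tested, and with a 2-fold minimum 1071 and 10. Removing the length trend gave 1308 called genes, 1130 of them in common, and leaving out shared 3′ ends gave 1400.

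With the replicate number as a block 193 genes passed (60 higher, 133 lower, 8 acute phase), on fewer degrees of freedom. With adjusted p below 0.01, 54 passed (21 higher, 33 lower, 2 acute phase). Library weights gave 3266 (1432 higher, 1834 lower), and Tm4sf4 went to -0.24. Camera with an estimated correlation called 0 of 35 lists, and fry 17. The library set covariate gave 0 genes by limma (1788 at an unadjusted p below 0.05), 0 higher, 0 lower and 0 acute phase. So did the comparison within the 6 libraries of one set (999 at an unadjusted p below 0.05). Both compare T cell-low with T cell-high 2 and 4 alone, so their fold changes are the same by construction. In that contrast Cd5l went to -0.55, Csf1r to -0.60 and Ms4a1 (0.42 before) to -0.024. Within the 6 libraries the list Kupffer cells and macrophages turned to lower by camera, with a signed adjusted p of -0.0287, again against T cell-high 2 and 4 alone. Where no cause is given above, the cause was not tested.

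Leaving out 1 library gave 109 (without T cell-low 2) to 3633 (without T cell-low 1) called genes, 41 to 1722 higher and 68 to 1911 lower for the same libraries, and 2 (without T cell-low 4) to 18 (without T cell-low 1) acute phase genes. Ccl5, which did not pass, went from -0.23 without T cell-low 3 to 0.20 without T cell-low 2, Tm4sf4 from -0.16 without T cell-high 2 to 0.61 without T cell-low 3, and Ms4a1 from -0.0097 without T cell-high 1 to 0.79 without T cell-low 2. The measure of depth by group, the difference in genes above 0, went from -173 without T cell-low 1 to 137 without T cell-low 2. The planned tests on whole counts, 3 count-based tests and 1 further size-factor scaling, were not run, because the values are not whole reads. Scaled values without reads set no counting limit for weakly expressed genes.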

Other observations

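The tests in this part were chosen only after the results were seen. Several gene families that the lists hold in small part or not at all were lower in T cell-low livers. Of 13 carboxylesterases 7 fell and 0 rose (median -1.23), with Ces2a, which hydrolyses drugs and esters, at 745 ± 126 scaled counts (SD, n = 4) against 1587 ± 152 (n = 6, log2 fold change -1.10, adjusted p = 0.00843). Of 10 acyl-CoA thioesterases 6 fell (median -1.03, fry adjusted p = 1.5e-05; adjusted p = 0.054 with an estimated correlation), among them Acot3 at 75.9 ± 36.8 against 311 ± 86.5 (-2.12). With the library set as a covariate this family passed (fry adjusted p = 0.000501), as did carboxylesterases (0.0494), glucuronosyltransferases and aldehyde dehydrogenases (0.0272 each). Without the covariate, camera called none of these 3 further families with an estimated correlation (adjusted p = 0.147, 0.148 and 0.147). Sulfotransferases (0.111), guanylate-binding proteins (0.0766), complex I (0.0981), cytochrome oxidase (0.246), ATP synthase (0.128) and proteasome subunits (0.111) did not, and the medians of the last 4 shrank to -0.368, -0.229, -0.275 and -0.349. Of 15 aldehyde dehydrogenases 7 fell, with Aldh1a1, which oxidises retinal, at 1199 ± 1344 against 6576 ± 1574 (adjusted p = 0.00876). Of 13 glucuronosyltransferases 5 fell (median -1.17), and of 11 sulfotransferases 4 fell and 1 rose (median -1.07). Of 10 guanylate-binding protein genes 3 fell (median -1.15).

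Genes of the respiratory chain and proteasome were lower by less. Of 46 complex I subunits 13 fell and 0 rose (median -0.64, fry adjusted p = 0.00504), of 12 cytochrome oxidase subunits 2 fell and 1 rose (median -0.68), and of 17 ATP synthase subunits 4 fell (median -0.52). Of 47 proteasome subunits 9 fell and 1 rose (median -0.60), and of 80 ribosomal protein genes 5 rose and 0 fell (median 0.14, fry adjusted p = 0.357). With an estimated correlation camera called 0 of these families (adjusted p from 0.054 to 0.584), and fry called all of those above but ribosomal proteins. Transcript length goes with the fold change: the median was -0.276 in the fifth of genes with the shortest transcripts and 0.233 in the fifth with the longest. After removal of that trend the median of ATP synthase was -0.16, that of complex I -0.34 and that of cytochrome oxidase -0.30, and the last no longer passed (fry adjusted p = 0.144), nor did the sulfotransferases (fry adjusted p = 0.0816), while ribosomal proteins then passed (fry adjusted p = 0.0282).

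Cold-inducible RNA-binding protein genes were higher in T cell-low livers. Cirbp had 1102 ± 879 scaled counts against 75.8 ± 17.2 (3.14, adjusted p = 0.0199), with 77.4 in T cell-low 1, and Rbm3 had 567 ± 325 against 64.3 ± 22.4 (2.85, adjusted p = 0.0103). Among 17 chaperones of the heat shock factor 3 fell, Fkbp4 (-2.30), Chordc1 (-1.57) and Ahsa1 (-1.22). Socs2, a feedback inhibitor of growth hormone signalling, had 1358 ± 960 against 202 ± 89.8 (2.37, adjusted p = 0.0236). Other genes of that pathway did not rise with it. Cish (0.63, adjusted p = 0.413), Igf1 (0.11, adjusted p = 0.678), Stat5b (0.38, adjusted p = 0.245) and Ghr (-1.15, adjusted p = 0.0505) did not pass. Igfals fell (-1.04, adjusted p = 0.032). The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were listed at 0 in all 10 libraries, and Xist had 866 to 2097, which argues against a mix of sexes among them.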
